A study of Homo sapiens with 50 samples.

How the data were processed

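Occupancy by RNA polymerase II was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against RPB1, the largest subunit of the enzyme. The cells were the Flp-In T-REx derivative of HEK293 (called HEK here, a human embryonic kidney line) and K562 cells (a human erythroleukaemia line), each with and without heat shock. The labels describe 50 libraries. They tie 5 heat-shocked and 5 unshocked HEK RPB1 libraries to the HEK table, 3 per condition with scramble siRNA and 2 per condition with vehicle. They tie 2 heat-shocked and 2 unshocked K562 RPB1 libraries to the K562 table, and these carry no siRNA or vehicle label. The temperature and length of the heat shock are not given in the sources used here. Another 12 HEK RPB1 libraries were not analysed here. These had NELFE siRNA, cycloheximide (an inhibitor of translation, 30 µg/ml for 1.5 h) or NSC624206 (an inhibitor of the ubiquitin-activating enzyme E1, 2 µM for 0.5 h). Likewise 8 libraries of nascent RNA (PRO-seq), 12 K562 ChIP libraries for NELFA, NELFE and MAPK14 and 4 input libraries were not analysed here. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min, and 200 µg of chromatin went into each immunoprecipitation.

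Per the submitters' processing notes, the tools were cutadapt, Bowtie2, MACS2 and DESeq2 and the genome build was hg38. Their versions, parameters and order, the counting tool, the limits of a gene body and the rule by which genes entered a table are not given in the sources used here. Per the file headers, each table holds the authors' own DESeq2 comparison of RPB1 reads over gene bodies, with no values per library. The mean normalized count of a gene over all libraries of a comparison is a signal deposited by the authors, namely read counts divided by size factors. The log2 fold change and its standard error (SE) were deposited by the authors for each gene. The Wald statistic, a score deposited by the authors, equalled the log2 fold change divided by its SE to within 1.25e-08. The p-value and the adjusted p-value were deposited by the authors as well. Recomputed over the genes listed, Benjamini-Hochberg adjustment gave the deposited adjusted p-values to within 4.51e-10. A last column holds the authors' class of each gene in words. Its boundary between changed and unchanged genes was an adjusted p of 0.01, whereas 0.05 was used here. The tables do not name the numerator of the fold change. It was read as heat shock over no heat shock, since the labels name these conditions and the heat shock genes rise under that reading.

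The HEK table lists 7217 genes and the K562 table lists 6004. The mean normalized count ran from 4.57 to 35705 in HEK (median 1384) and from 7.58 to 190532 in K562 (median 1091). The total count of each library is unknown. The median SE of a log2 fold change was 0.15 in HEK and 0.20 in K562, and the simulation described below shows which sizes of change were called. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries only. The median log2 fold change was -0.41 in HEK and -0.38 in K562. Median-of-ratios scaling over the listed genes alone would place that median near 0, and the genes on which the authors' size factors rest are not given in the sources used here.

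The tests fixed before the data were examined assumed read counts per library. The tables hold the authors' results instead, and the branch written for that case was used. A gene was called at the authors' adjusted p under 0.05. Of the gene identifiers, 7198 in HEK and 5983 in K562 were found in the reference table of gene names. Positions and lengths came from the RefSeq annotation of GRCh38, the assembly of hg38, matched by gene symbol for 6940 HEK and 5727 K562 genes. Before the data were examined, 24 gene lists had been written down. Each list with at least 3 listed members was tested against all other listed genes with limma's cameraPR on the authors' Wald statistic. The preset correlation between genes was 0.01, the test was two-sided, and p-values were adjusted over 22 lists by the Benjamini-Hochberg method. No correlation could be estimated and fry could not be run without values per library. The cell lines were compared by the correlation of log2 fold changes across genes, by Fisher's exact test of overlap (two-sided) and by a test of each gene's difference in fold change. That last test divided the difference by the root of the summed squared SEs and was adjusted over 4753 genes. The tables were normalized separately, so the difference was also computed after each table's median fold change had been subtracted. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.

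The genes named were set by a rule written before the data were examined. For each cell line they were the 8 largest increases and 8 largest decreases among genes with an adjusted p under 0.05 and a mean normalized count of at least 100. Up to 3 members of each list with the smallest p were added, and HSPA1A, HSPA1B, DNAJB1, HSPH1, HSPA8, NELFE, POLR2A, UBA1 and MYC wherever a table listed them. Genes without a symbol or with clone-style names were skipped. Some genes that the rule takes are not reported here and were not replaced. Other genes are named with the statement that they were chosen after their values were seen, or because they complete a group.

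The alternatives planned for tables of this kind were an adjusted p of 0.01, an absolute log2 fold change of at least 1 beside the adjusted p of 0.05, and a mean normalized count of at least 100. Centring (subtraction of each table's median log2 fold change), a preset correlation of 0.05, ranks in place of the statistic and a correlation without the chaperone list were added after the data had been seen. Other normalizations, other count tests, single libraries left out, other splits of the libraries and the contrast of scramble siRNA with vehicle all need values per library and were not run. The calculations were tested on simulated data with the real standard errors, a common offset and 200 changed genes, and genes there were called after centring. In HEK (7217 genes), 47.6% of changes of 0.5 on the log2 scale, 97.0% of changes of 1 and 100% of changes of 2 were called with the right sign, and 0.602% of calls were false. In K562 (6004 genes) these shares were 30.2%, 81.4% and 100%, and 4.61% of calls were false. In each line both shifted lists and 0 of 20 null lists were called. Genes were simulated independently of each other, so this does not show how the list test behaves when list members are correlated. As deposited, 65.4% of HEK and 51.4% of K562 genes were called, so the simulated shares do not give the power of the reported calls.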

Results

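Heat shock makes human cells transcribe chaperone genes while transcription of many other genes declines, and the series asks which steps that decline depends on. The data analysed here are the authors' comparisons of RPB1 ChIP-seq over gene bodies, heat shock against no heat shock, in HEK cells (5 libraries against 5) and in K562 cells (2 against 2). RPB1 reads over a gene body report how much RNA polymerase II occupies that gene, not the level of its RNA. Log2 fold changes, standard errors (SE) and adjusted p-values of single genes are those of the authors' DESeq2 tests. Positions are in hg38. The median gene listed had a mean normalized count of 1384 in HEK and 1091 in K562.

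In HEK cells, RPB1 rose over most listed HSF1-dependent chaperone genes and fell over most other genes listed. HSPH1, which encodes a nucleotide exchange factor for HSP70 (ENSG00000120694.19, chromosome 13, 31134973 to 31162388), rose by 4.51 on the log2 scale (SE 0.19, adjusted p = 7.71e-127) in the authors' deposited table, a 22.8-fold increase. DNAJB1, which encodes an HSP40 co-chaperone (ENSG00000132002.7, chromosome 19, 14514769 to 14560391), rose by 4.40 (SE 0.17, adjusted p = 1.30e-142) in the authors' deposited table. SERPINH1, the collagen chaperone HSP47 (chromosome 11, 75562253 to 75572783), rose by 3.67 (SE 0.23) and HSPA1B, an inducible HSP70 gene (ENSG00000204388.6, chromosome 6, 31827738 to 31830254), by 3.36 (SE 0.19) in the authors' deposited table. HSP47 resides in the endoplasmic reticulum, although SERPINH1 belongs to the chaperone list that is named cytosolic here. HSPA1B shares nearly its whole sequence with its neighbour HSPA1A, which is not listed, so its value is uncertain. BAG3, a co-chaperone of HSP70, rose by 2.73 (SE 0.18) and HSPA8, the constitutive HSC70 gene, by 1.19 (SE 0.19) in the authors' deposited table.

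Of the 14 listed members of the HSF1-dependent cytosolic chaperone list, 11 were higher and 1, DNAJA4, was lower, with 11 higher and none lower after centring, and the list stood above all other genes (cameraPR, adjusted p = 1.11e-36). The remaining large increases named by rule lay outside that list. They were PNLDC1, a poly(A) exonuclease gene (3.31, SE 0.22), CLU, which encodes the extracellular chaperone clusterin (2.71, SE 0.17), and NUCB1, which encodes the calcium-binding protein nucleobindin (2.59, SE 0.22), all in the authors' deposited table. In total 584 of the 7217 HEK genes were higher and 4137 were lower at an adjusted p under 0.05. The balance depends on where 0 lies. With the median log2 fold change of -0.41 subtracted from each gene, 1858 were higher and 1739 lower, and counts under that centring are given below beside those as deposited.

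Genes of the translation apparatus lost RPB1 in HEK cells. Of 35 cytosolic ribosomal protein genes, 34 were lower and 1 was higher (adjusted p = 5.71e-05 for the list), with 28 lower and 1 higher after centring. RPS19 (chromosome 19, 41860255 to 41872925) changed by -2.45 (SE 0.21), RPS23 by -1.67 (SE 0.19) and RPL22 by -1.09 (SE 0.10) in the authors' deposited table. The exception was RPL3L, a paralogue of RPL3 known from striated muscle, at 1.13 in the authors' deposited table. Of 10 translation initiation and elongation factor genes, 9 were lower, with 8 lower after centring (adjusted p = 0.0127 for the list, and 0.0589 with a preset correlation of 0.05, which ends the call). EEF1A1, the elongation factor that delivers aminoacyl-tRNA, changed by -1.95 (SE 0.21) and EIF3A, a subunit of initiation factor eIF3, by -1.07 (SE 0.10) in the authors' deposited table. EIF3M fell by 0.69 (SE 0.08) in the authors' deposited table. SNHG5, a host gene of small nucleolar RNAs, fell by 2.43 (SE 0.29) in the authors' deposited table.

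Most listed splicing, cell cycle and DNA repair genes also fell in HEK cells, and these lists were called lower than other genes only at the preset correlation of 0.01. Of 19 splicing factor and hnRNP genes, 18 were lower and 12 after centring (adjusted p = 0.0127 for the list, 0.0730 with a preset correlation of 0.05). SRSF6 changed by -2.01 (SE 0.22), U2AF1 by -1.08 (SE 0.13) and SRSF9 by -0.71 (SE 0.09) in the authors' deposited table. Of 18 cell cycle genes, 16 were lower, and after centring 10 were lower and 2 higher (adjusted p = 0.0467 for the list). The adjusted p of this list was 0.165 with a preset correlation of 0.05, 0.0570 with ranks and 0.0612 with a mean normalized count of at least 100. The mitotic cyclin CCNB1 changed by -1.54 (SE 0.18), the G1/S cyclin CCNE1 by -1.43 (SE 0.14) and the proliferation marker MKI67 by -1.16 (SE 0.10) in the authors' deposited table. Of 9 DNA repair genes, 8 were lower and 5 after centring (adjusted p = 0.0127 for the list, 0.0604 after centring, 0.0589 with a preset correlation of 0.05). FANCA, of the Fanconi anaemia core complex, changed by -1.12 (SE 0.10), XRCC5, the Ku80 gene, by -0.86 (SE 0.09) and PARP1 by -0.82 (SE 0.07) in the authors' deposited table.

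Ubiquitin pathway genes were part of the decline in HEK cells. Of 19 genes of ubiquitin activation and nascent-protein quality control, 14 were lower and none was higher, whereas after centring 9 were lower and 4 higher. The adjusted p of the list was 0.0127, and the call was lost after centring (adjusted p = 0.0604), with a preset correlation of 0.05 (0.0630) and with ranks (0.0574). TCF25, of the ribosome quality control complex, changed by -1.68 (SE 0.12), the ubiquitin ligase gene HUWE1 by -1.26 (SE 0.08) and the conjugating enzyme gene UBE2D2 by -0.99 (SE 0.09) in the authors' deposited table. UBA1, which encodes the ubiquitin-activating enzyme itself, fell by 0.66 (SE 0.18, adjusted p = 0.000507) in the authors' deposited table, a change that did not pass the threshold after centring (-0.25). Among 10 genes of pausing and elongation factors, 9 were lower, and after centring 3 were lower and 1 higher (adjusted p = 0.232 for the list). NELFA changed by -1.32 (SE 0.18), LEO1 by -1.19 (SE 0.15) and CCNT1, the cyclin of P-TEFb, by -0.81 (SE 0.11) in the authors' deposited table. NELFE stood at 0.23 (SE 0.16, adjusted p = 0.182) in the authors' deposited table.

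Several other HEK groups had mostly lower members without standing apart from other genes. For proteasome subunits, 13 of 18 were lower, led by PSMC4 (-1.04), PSMD8 (-1.17) and PSMD12 (-0.54) in the authors' deposited table (adjusted p = 0.108 for the list). For oxidative phosphorylation, 17 of 27 were lower, with COX5A at -1.11, COX6C at -0.71 and NDUFAB1 at -0.48 in the authors' deposited table (adjusted p = 0.614). For mitochondrial ribosomal proteins, 18 of 27 were lower and 2 higher, with MRPS14 at 2.08, MRPL15 at -1.28 and MRPS15 at -0.82 in the authors' deposited table (adjusted p = 0.917). Mediator and general transcription factor genes were lower in 11 of 12 cases, with TAF4 at -0.60, MED4 at -0.62 and MED23 at -0.70 in the authors' deposited table (adjusted p = 0.200). Glycolysis genes were lower in 5 of 7 cases, with PFKL at -1.43, LDHB at -0.92 and HK1 at -0.67 in the authors' deposited table (adjusted p = 0.200). RNA polymerase II subunit genes were lower in 3 of 5 cases, with POLR2H at -1.37, POLR2D at -0.42 and POLR2E at -0.38 in the authors' deposited table (adjusted p = 0.942), and after centring POLR2E stood at 0.03. After centring these 6 lists held 6, 5, 5, 1, 3 and 1 lower and 2, 4, 6, 0, 1 and 0 higher members, in the order given.

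Of the stress-response and marker lists in HEK cells, p53 targets and the cytoskeleton had lower members and none higher, and as deposited the other tested lists had called members in both directions. Of 12 immediate early genes, 2 were higher and 4 lower, with KLF6 at 0.82, EGR2 at -1.53 and CCNL1 at -1.44 in the authors' deposited table (adjusted p = 0.232 for the list). Of 7 genes of endoplasmic reticulum chaperones and the unfolded protein response, 1 was higher and 3 lower, with CANX at -0.70, TRIB3 at -0.69 and HYOU1 at -0.65 in the authors' deposited table (adjusted p = 0.402). Of 10 NRF2 targets, 1 was higher and 4 lower, with NQO1 at 0.60, GCLC at -0.68 and TXN at -1.77 in the authors' deposited table (adjusted p = 0.402). Of 6 p53 targets, 3 were lower, namely MDM2 at -1.82, BBC3 at -0.91 and ZMAT3 at -0.52 in the authors' deposited table (adjusted p = 0.555). Of 8 cholesterol synthesis genes, 2 were higher and 3 lower, with HSD17B7 at 1.19, FDFT1 at -0.65 and SC5D at -0.81 in the authors' deposited table (adjusted p = 0.232). Of 4 cytoskeleton genes, 3 were lower, namely TUBB2A at -2.18, ACTB at -1.10 and FLNA at -0.89 in the authors' deposited table (adjusted p = 0.467). Of 12 renal, neuronal and epithelial markers, 1 was higher and 5 lower, with NEFL at -1.19, KRT8 at -1.16 and INA at -0.79 in the authors' deposited table (adjusted p = 0.515). Of 6 erythroid and megakaryocytic markers, 2 were higher and 3 lower, with ANK1 at 0.50, LYN at -0.52 and EPOR at -1.19 in the authors' deposited table (adjusted p = 0.402). The TRiC chaperonin and replication-dependent histone lists had 2 listed members each and were not tested, with CCT7 at -0.24, CCT8 at -0.01, HIST1H4H at -0.30 and HIST2H2BF at -0.20 in the authors' deposited table, none of which was called. After centring, higher and lower members numbered 3 and 2 for immediate early genes, 1 and 0 for endoplasmic reticulum genes, 3 and 1 for NRF2 targets, 0 and 2 for p53 targets and 2 and 0 for cholesterol synthesis. They numbered 0 and 3 for the cytoskeleton, 4 and 2 for the HEK-type markers, 2 and 2 for the erythroid markers, 1 and 0 for TRiC (CCT8, chosen after its value was seen) and 0 and 0 for histones.

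The remaining large HEK decreases named by rule belong to no list. ZNF711, a zinc finger gene on the X chromosome, changed by -2.80 (SE 0.28), MFSD7, a transporter gene, by -2.79 (SE 0.17) and NDRG1, a gene induced by stress and hypoxia, by -2.59 (SE 0.19) in the authors' deposited table. TUBGCP5, of the gamma-tubulin ring complex, fell by 2.40 (SE 0.20) in the authors' deposited table. The pseudogenes ALG1L12P and ALG1L11P changed by -2.73 (SE 0.20) and -2.64 (SE 0.22) in the authors' deposited table, but they are near-identical copies and their values are uncertain. Adjusted over the list alone, each of the 24 HEK lists had the same counts of higher and lower members as over all genes.

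In K562 cells the chaperone genes gained the most RPB1, with the highest median among the lists as deposited and a rise in each listed member. HSPA1B rose by 6.91 (SE 0.17), a 120.2-fold increase, DNAJB1 by 6.29 (SE 0.16) and HSPH1 by 6.20 (SE 0.15), each with an adjusted p listed as 0 in the authors' deposited table. HSP90AA1, the inducible HSP90 gene (chromosome 14, 102080742 to 102139749), rose by 5.38 (SE 0.14), SERPINH1 by 4.97 (SE 0.17) and BAG3 by 4.36 (SE 0.19) in the authors' deposited table. All 13 listed members of the chaperone list were higher, as they were after centring (adjusted p = 2.00e-146 for the list). Both listed TRiC chaperonin genes were higher as well, CCT7 by 0.91 (SE 0.22) and CCT2 by 0.64 (SE 0.19) in the authors' deposited table. Of the 6004 K562 genes, 535 were higher and 2550 lower, and after the median of -0.38 was subtracted 1218 were higher and 1048 lower.

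Immediate early genes moved far in both directions in K562 cells. DUSP1, a phosphatase of MAP kinases (chromosome 5, 172768096 to 172771195), rose by 4.03 (SE 0.33) and IER5 by 3.93 (SE 0.25), while the transcription factor gene EGR1 (chromosome 5, 138465479 to 138469303) fell by 3.25 (SE 0.34) in the authors' deposited table. Of 14 listed members 4 were higher and 3 lower, and after centring 5 and 3 (adjusted p = 0.0331 for the list in the upward direction). That call was lost after centring (adjusted p = 0.1000), with a preset correlation of 0.05 (0.103) and with ranks (0.202). The median of the list was -0.07 although its mean was 0.26, because the largest increases outweighed the falls. MYC stood at -0.15 (SE 0.23, adjusted p = 0.598) in the authors' deposited table.

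Members of the erythroid and megakaryocytic marker list were higher or lower gene by gene in K562 cells. HEMGN, a regulator of erythroid differentiation, rose by 1.01 (SE 0.15) in the authors' deposited table. PTPRC, listed there although it encodes the leukocyte antigen CD45 and not an erythroid protein, fell by 0.91 (SE 0.14) in the authors' deposited table. It was chosen after its value was seen. Of 10 listed erythroid and megakaryocytic markers, 5 were higher and 4 lower, and after centring 5 and 1 (adjusted p = 0.0414 for the list in the upward direction). With a preset correlation of 0.05 (adjusted p = 0.103) and with ranks (0.381) that call was lost. Cholesterol synthesis genes rose as a list, with 3 of 6 higher and none lower, and 4 higher after centring (adjusted p = 0.00118). HSD17B7 rose by 1.84 (SE 0.23) and MSMO1 by 1.58 (SE 0.18) in the authors' deposited table.

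Translation genes fell in K562 cells. Of 33 cytosolic ribosomal protein genes, 29 were lower and none was higher, with 26 lower after centring (adjusted p = 4.75e-10 for the list). RPS12 changed by -3.00 (SE 0.33), RPL22L1 by -2.93 (SE 0.30), RPL13A by -2.75 (SE 0.25), RPS19 by -2.44 (SE 0.20) and RPS3 by -1.93 (SE 0.19) in the authors' deposited table. Of 12 translation factor genes, 10 were lower and 1 higher, and after centring 8 and 1 (adjusted p = 0.000562 for the list). EEF1A1 changed by -2.33 (SE 0.20), EEF2, the translocation factor, by -2.13 (SE 0.19) and EIF3D by -1.69 (SE 0.16) in the authors' deposited table. SNHG5 changed by -3.25 (SE 0.20) and TUBGCP5 by -2.84 (SE 0.20) in the authors' deposited table. ANPEP, an aminopeptidase gene, fell by 2.75 (SE 0.34) in the authors' deposited table.

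The other K562 lists were not called against the remaining genes as tested, and DNA repair was called lower with ranks alone (adjusted p = 0.0172). Of 17 ubiquitin and quality control genes, 3 were higher and 3 lower, and after centring 6 were higher and 1 lower (adjusted p = 0.531 for the list), with UBE2N at 0.65, UBE2D2 at -0.66, RACK1 at -1.24 and UBA1 at -0.07 in the authors' deposited table. Of 16 splicing genes, 1 was higher and 10 lower, with the splicing kinase gene CLK1 at 1.56, SRSF10 at -1.63 and U2AF1 at -0.93 in the authors' deposited table (adjusted p = 0.639). Of 19 cell cycle genes, 2 were higher and 14 lower, with the ribonucleotide reductase genes RRM2 at -1.52 and RRM1 at -1.49 and CDK1 at -0.996 in the authors' deposited table (adjusted p = 0.189). All 8 DNA repair genes were lower, led by NBN at -1.26, ERCC2 at -1.56 and FANCA at -0.95 in the authors' deposited table (adjusted p = 0.0610). Of 24 oxidative phosphorylation genes, 1 was higher and 12 lower, with NDUFA5 at -1.21, NDUFV3 at -1.21 and COX7B at -1.31 in the authors' deposited table (adjusted p = 0.349). Of 29 mitochondrial ribosomal protein genes, 2 were higher and 10 lower, with MRPS14 at 2.55, MRPL42 at -1.26 and MRPL15 at -1.49 in the authors' deposited table (adjusted p = 0.876). Of 15 proteasome genes 8 were lower, with PSMB2 at -1.29, PSMC3 at -0.86 and PSMB5 at -0.94 in the authors' deposited table (adjusted p = 0.556). After centring these 6 lists from splicing to proteasome held 3, 2, 0, 3, 6 and 1 higher and 2, 7, 3, 6, 4 and 2 lower members.

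Of 8 glycolysis genes, 1 was higher and 3 lower in K562, with PGK1 at 1.50, PFKL at -1.18 and HK2 at -1.16 in the authors' deposited table (adjusted p = 0.862). Of 9 pausing and elongation factor genes 3 were lower, namely LEO1 at -1.32, CCNT1 at -0.72 and NELFB at -0.61 in the authors' deposited table (adjusted p = 0.862). Of 4 RNA polymerase II subunit genes 2 were lower, POLR2H at -1.45 and POLR2D at -0.61, with POLR2G at -0.77 not called in the authors' deposited table (adjusted p = 0.876). Of 14 Mediator and general transcription factor genes, 1 was higher and 9 lower, with MED23 at -0.81, GTF2B at -0.78 and MED24 at -0.78 in the authors' deposited table (adjusted p = 0.587). Of 7 endoplasmic reticulum stress genes 5 were lower, led by TRIB3 at -2.10, ASNS at -0.99 and PDIA4 at -0.88 in the authors' deposited table (adjusted p = 0.556). Of 8 NRF2 targets, 1 was higher and 4 lower, with TXN at -0.86, SLC7A11 at -0.89 and GCLC at -0.65 in the authors' deposited table (adjusted p = 0.862). Of 8 p53 targets, 1 was higher and 5 lower, with CDKN1A at 0.88, MDM2 at -1.11 and BBC3 at -1.57 in the authors' deposited table (adjusted p = 0.860). Of 8 cytoskeleton genes 2 were higher and 2 lower, with MYH9 at 1.06, TPM1 at 0.73 and TPM3 at -0.55 in the authors' deposited table (adjusted p = 0.499). Of 5 HEK-type markers 2 were lower, MAP1B at -1.13 and GDF15 at -0.78, with NES at 0.55 not called in the authors' deposited table (adjusted p = 0.876). Both listed histone genes were lower, HIST1H4H at -0.88 and HIST1H2BN at -0.63 in the authors' deposited table. Adjusted over the list alone, counts in K562 equalled those over all genes except for oxidative phosphorylation (13 lower) and the cytoskeleton (3 lower). After centring, higher and lower members numbered 2 and 2 for glycolysis, 2 and 1 for pausing factors, 1 and 1 for RNA polymerase II, 2 and 1 for Mediator and general factors and 0 and 2 for endoplasmic reticulum genes. They numbered 3 and 0 for NRF2 targets, 1 and 2 for p53 targets, 2 and 0 for the cytoskeleton, 1 and 1 for the HEK-type markers and 0 and 0 for histones. The NRF2 list had a median of -0.62, below that of all genes (-0.38), while its mean was -0.28 and its test pointed upward.

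**Figure D1:**
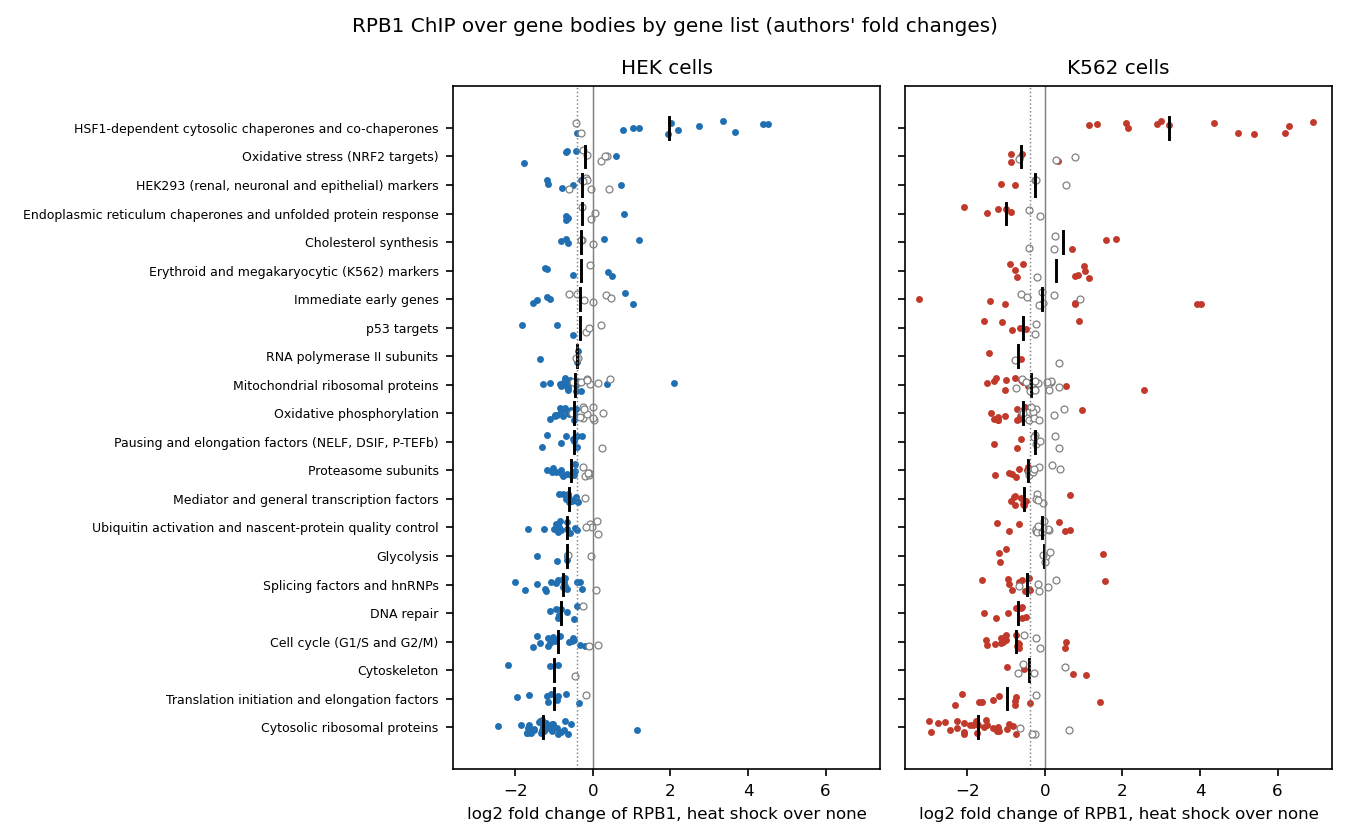
Log2 fold change of RPB1 over gene bodies (horizontal axis, heat shock over no heat shock, as deposited by the authors) for the members of 22 gene lists in HEK (left) and K562 cells (right). Filled points passed an adjusted p of 0.05, open points did not, black bars mark list medians and the dotted line marks the median of all genes (-0.41 in HEK, -0.38 in K562) in a panel, with chaperones to the right (medians of 1.97 and 3.20) and the cytosolic ribosomal proteins farthest to the left (-1.28 and -1.73).

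The chaperone list rose and the ribosomal protein and translation factor lists fell in both cell lines, with DNAJA4 and RPL3L in HEK among the members that went the other way. Over the 4753 genes listed in both tables, the log2 fold changes correlated across genes with a Pearson r of 0.548 and a Spearman rho of 0.464, where genes are not independent replicates and no p is given. Lower in both lines were 1713 genes, against 1356 if the calls were independent (Fisher's exact test, odds ratio 4.31, p = 8.34e-111). Higher in both were 126 genes, against 27.5 if independent (Fisher's exact test, odds ratio 9.56, p = 2.66e-57). Both tests treat genes as independent, which they are not, so their p-values are nominal. After centring, 491 genes were lower and 410 higher in both. Calls in opposite directions were rarer than independence would give, with 112 genes lower in HEK and higher in K562 (265.5 if independent) and 35 the other way (140.3 if independent).

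The fold change differed between the lines for several groups, which the test of the difference addresses. It is a ratio to the unshocked level of each line, and those levels were not compared. All 11 chaperone genes listed in both tables had the lower value in HEK, with a median difference (HEK minus K562) of -1.32 and all 11 differences called (adjusted p = 8.24e-15 for the list). The cytosolic ribosomal protein genes had the less negative value in HEK for 20 of 27 members, with a median of -1.28 against -1.74 over 27 shared genes (adjusted p = 0.00968). Gene by gene, only 4 of these 27 differences were called, all more positive in HEK. The ubiquitin and quality control genes had the more negative value in HEK for 13 of 17 members, with a median of -0.66 against -0.08 over 17 shared genes and 8 called differences, all more negative in HEK (adjusted p = 0.0136). The endoplasmic reticulum stress genes had a median of -0.05 in HEK against -0.99 in K562 over 5 shared genes (adjusted p = 0.0496, and 0.0564 after centring and 0.0637 with ranks). With a preset correlation of 0.05 the chaperone difference stayed called, and those of the ribosomal protein, ubiquitin and endoplasmic reticulum lists did not (adjusted p = 0.0827 for each). Gene by gene, 352 of 4753 fold changes were more positive and 822 more negative in HEK, and with each median subtracted 399 and 734. The tables were scaled separately, and the lines rest on unequal numbers of libraries. The HEK cells had scramble siRNA or vehicle and the K562 cells neither, so line and treatment cannot be told apart.

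**Figure D2:**
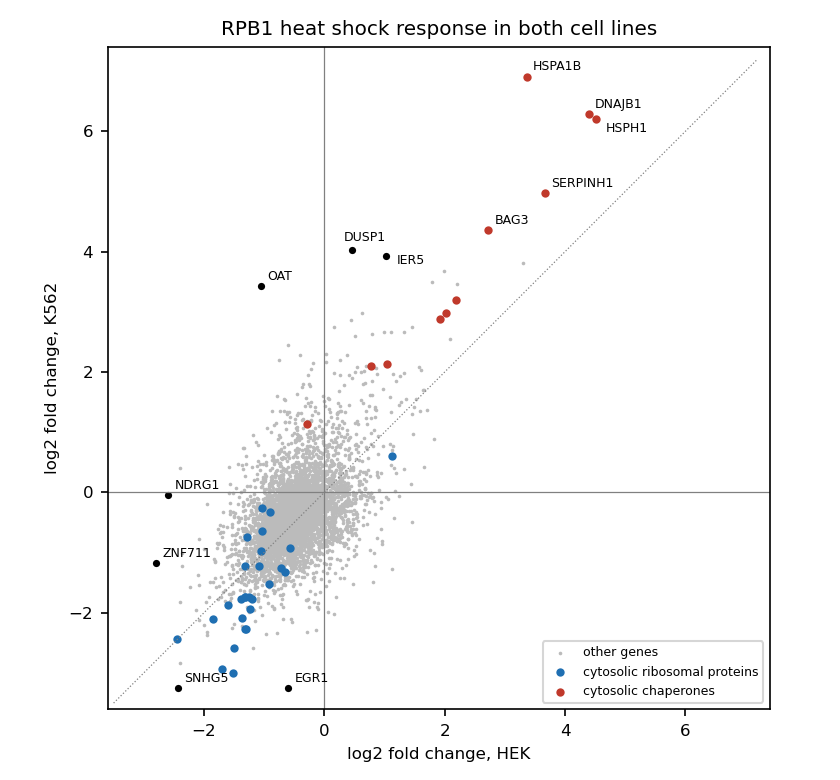
Log2 fold change of RPB1 in K562 (vertical axis) against HEK (horizontal axis) for the 4753 genes in both tables, with the chaperone list in red, cytosolic ribosomal proteins in blue, other genes in grey and other labelled genes in black. Chaperone genes lie above the dotted line of equal change (HSPA1B at 3.36 in HEK and 6.91 in K562), and most ribosomal protein genes lie below 0 on both axes.

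The longest genes had less negative changes in RPB1 than shorter genes, a trend looked for after the tables had been seen that in K562 was absent among genes of like count. Among the eighth of HEK genes with the longest annotated spans (at least 166 kb), the median log2 fold change was -0.13 and 32.0% of genes were lower. Among the shortest eighth (up to 8.94 kb) these values were -0.50 and 51.8%. In K562 the longest eighth (at least 138 kb) had a median of -0.16 with 21.1% lower, and the shortest (up to 8.88 kb) a median of -0.47 with 32.8% lower. Across genes, length and fold change had a Spearman rho of 0.211 in HEK and 0.163 in K562, and genes are not independent replicates. Within 10 groups of like mean normalized count the median rho was 0.260 in HEK and -0.0391 in K562. Among genes at or below the median length rho was -0.0313 in HEK and -0.0536 in K562, so the trend lay in the longer genes.

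**Figure D3:**
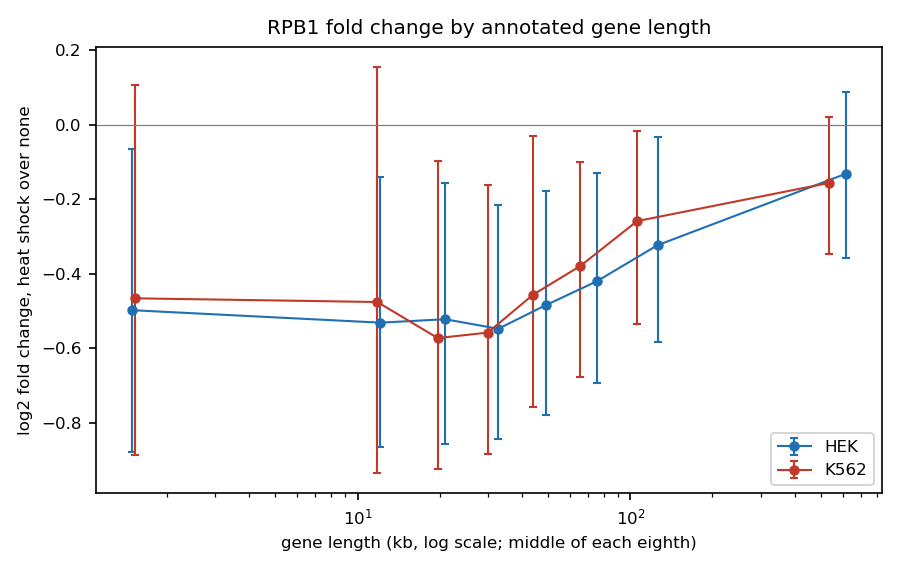
Median log2 fold change of RPB1 (vertical axis, bars span the quartiles) in 8 groups of equal gene number ordered by annotated gene length (horizontal axis, kb, log scale) for HEK (blue) and K562 (red). Medians stay near -0.50 up to a length of about 40.4 kb in HEK and rise to -0.13 in the longest genes.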

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

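The fold changes of the chaperone-list genes were smaller in HEK than in K562 cells, and single genes of other lists also changed by different amounts. Each fold change is a ratio to the line's own unshocked level. Those levels were not compared, so a smaller ratio does not show less RPB1 after heat shock. The tests of the difference between lines, over genes and over lists, were chosen only after the tables had been seen, as was centring. All differences are HEK minus K562 of the authors' log2 fold changes, and their causes were not tested. Only the HEK cells had scramble siRNA or vehicle, so line and treatment cannot be told apart. Of 4753 genes, 352 had a more positive and 822 a more negative change in HEK, with 399 and 734 after centring. The lists that differed were the chaperones (adjusted p = 8.24e-15), cytosolic ribosomal proteins (0.00968), ubiquitin and quality control genes (0.0136) and endoplasmic reticulum stress genes (0.0496). With a preset correlation of 0.05 the chaperones stayed called and the adjusted p of each of the other lists was 0.0827. The endoplasmic reticulum list was also lost with ranks (0.0637) and after centring (0.0564).

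Of 94 named genes in both tables, a difference was called for 33, and 32 of these after centring, when SRSF6 no longer passed. Heat shock genes had smaller fold changes in HEK, with a difference of -3.55 for HSPA1B, -1.89 for DNAJB1, -1.69 for HSPH1, -1.64 for BAG3 and -1.31 for SERPINH1. The chaperonin gene CCT7 differed by -1.15. The immediate early genes DUSP1 and IER5 differed by -3.57 and -2.90, whereas EGR1, which fell in K562, differed by 2.65. In HEK neither EGR1 at -0.60 (SE 0.38) nor DUSP1 at 0.46 (SE 0.31) was clearly changed in the authors' deposited table. NDRG1 differed by -2.55, with -2.59 in HEK and -0.05 in K562 in the authors' deposited table. The zinc finger gene ZNF711 differed by -1.63. In the ubiquitin list, UBE2N differed by -1.11 and HUWE1 by -1.06. More negative in HEK were also the splicing genes CLK1 (-1.48), SRSF6 (-1.06) and SRSF9 (-1.01), the pausing factor gene NELFA (-1.04), the polymerase subunit gene POLR2E (-0.76) and the proteasome gene PSMC4 (-0.61). The cholesterol synthesis gene MSMO1 differed by -1.87, the p53 targets CDKN1A and MDM2 by -1.05 and -0.71, the glycolysis genes LDHB and HK1 by -0.86 and -0.70 and the thioredoxin gene TXN by -0.90. More positive in HEK were RPS12 (1.48), RPL22L1 (1.24), RPS3 (0.69) and EEF2 (0.98) of the translation apparatus. The same held for TRIB3 (1.41) and PDIA4 (0.83) of the endoplasmic reticulum list, the cystine transporter gene SLC7A11 (1.21) and the ribonucleotide reductase gene RRM1 (0.64).

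Opposite calls in the lines, with a called difference, were found for 147 genes, and for 29 of these also after centring. The following were chosen after their values were seen. OAT, the ornithine aminotransferase gene, fell by 1.05 (SE 0.17) in HEK and rose by 3.43 (SE 0.16) in K562 in the authors' deposited table, a difference of -4.48. PRDX6, a peroxiredoxin gene (-2.13), AHCTF1, a nucleoporin gene (-1.90), TSPYL2 (-2.22) and TCTE1 (-1.96) also fell in HEK and rose in K562. The reverse held for SKIDA1 (2.40), the carnitine palmitoyltransferase gene CPT1A (1.82), the phospholipase gene PLD1 (1.83), ZNF227 (1.56) and the gasdermin gene GSDMA (1.18). After centring the opposite calls held for OAT, PRDX6, AHCTF1, SKIDA1 and PLD1, and were lost for TSPYL2 and TCTE1 in HEK and for CPT1A, ZNF227 and GSDMA in K562. HSPA1B is nearly identical to HSPA1A, so the size of its difference is uncertain.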

How the results depend on the processing

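Centring, the preset correlation of 0.05, ranks and the correlation without chaperones were chosen after the data had been seen. No paired analysis was possible because the tables hold no values per library. For the same reason DESeq2 and edgeR fits, their size factors, total-count scaling, no filter, a replicate block, a fit without a treatment term, treatment subsets, leave-one-out, other splits of the libraries, an estimated correlation, fry, scramble against vehicle and the inhibitor and NELFE siRNA comparisons were not run. Depth per library is unknown, and the median SE (0.15 in HEK, 0.20 in K562) limits what could be called.

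With an absolute log2 fold change of at least 1, which by construction calls fewer genes, 89 were higher and 830 lower in HEK and 230 higher and 789 lower in K562, and 117 differences were more positive and 316 more negative in HEK. Centred, 1858 were higher and 1739 lower in HEK and 1218 higher and 1048 lower in K562, which follows from the subtracted median. An adjusted p of 0.01 left 190 more positive and 525 more negative differences, by its stricter threshold. With a mean normalized count of at least 100, Pearson's r across genes was 0.578 and Spearman's rho 0.493, and without the chaperone list r was 0.505. The odds ratios of overlap stayed above 1 with each alternative run, from 4.28 to 6.87 for lower genes and 4.09 to 59.0 for higher genes.

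For HEK lists, 6 were lower as reported, and 1 at an adjusted p of 0.01 or with the preset correlation of 0.05. For K562 lists, 4 were higher as reported, and 2 at 0.01, with the preset correlation of 0.05 or with ranks of the Wald statistic. For HEK minus K562, 2 lists were higher as reported, 1 at 0.01, with ranks or with centred fold changes, and 0 with the preset correlation of 0.05. Lists lower in that comparison went from 2 to 1 at 0.01 or with the preset correlation of 0.05. Apart from the construction of each alternative, the cause was not tested. Of 163 named values, 160 kept direction and call at 0.01, 105 with the absolute change of at least 1, 163 with the mean count of at least 100 and 129 after centring. After centring 30 lost and 3 gained a call, and POLR2E in HEK went from -0.38 in the authors' deposited table to 0.0292.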

Other observations

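The authors' class Top Downregulated held ribosomal protein, translation, cell cycle and immediate early genes in both lines. It held 245 HEK and 191 K562 genes, and how they were chosen is not given in the sources used here. It is not the set of the largest decreases, since 585 HEK and 566 K562 genes that fell by at least 1 on the log2 scale are in the plain class Downregulated, and 12 K562 genes of the Top class fell by less. Yet all 245 HEK and 179 of the 191 K562 genes of the Top class fell by at least 1. Of the plain class only 585 of 3380 in HEK and 566 of 1801 in K562 did. The tests below took all other decreased genes as background, so they do not separate membership of the class from the size of the fall. Of the cytosolic ribosomal protein genes of either decreased class, 27 of 34 in HEK and 25 of 27 in K562 were in it (Fisher's exact test against other decreased genes, adjusted p = 7.84e-25 and 4.08e-23, odds ratios 59.7 and 135). Of the translation factors, 4 of 8 in HEK and 5 of 10 in K562 were in it (adjusted p = 0.00569 in each by Fisher's exact test), EEF1A1, EEF2 and EIF3D in both lines. Among cell cycle genes, the kinase gene AURKB, the cyclin gene CCNB1 and the ribonucleotide reductase gene RRM2 were in the class in both lines, of 5 of 13 decreased members in each (Fisher's exact test, adjusted p = 0.00569 in HEK and 0.0183 in K562). Immediate early members were EGR2, FOSB and KLF4 in HEK, 3 of 4 decreased, and EGR1, FOSL1 and CCNL1 in K562, 3 of 3 (adjusted p = 0.00569 in each by Fisher's exact test). In K562 the class also held 5 of 11 decreased oxidative phosphorylation genes (Fisher's exact test, adjusted p = 0.00855) and 3 of 5 endoplasmic reticulum stress genes (Fisher's exact test, adjusted p = 0.0239). Of the splicing genes, HNRNPH1, SRSF3, SRSF5, SRSF6, SRSF10 and U2AF1 were in the class in HEK, 6 of 17 decreased members (Fisher's exact test, adjusted p = 0.00569). In K562 SRSF10 was, 1 of 6 decreased members, and the lines were not tested against each other. The class in HEK also held 2 of 3 decreased cytoskeleton genes, TUBB2A and ACTB (Fisher's exact test, adjusted p = 0.0380).

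Genes of this class were short. Their median annotated length was 9.95 kb in HEK against 39.1 kb for the other decreased genes, and 12.2 kb against 35.2 kb in K562. The gap was smaller against plain Downregulated genes that fell by at least 1, with medians of 29.1 kb in HEK and 25.3 kb in K562. The class shared 61 genes between lines, against 5.22 if membership were independent among all genes in both tables and 10.3 among the 1312 genes lower in both at an adjusted p under 0.01 (Fisher's exact test, p = 4.25e-53 and 4.31e-40). Neither baseline matched genes by the size of their fall. Lower by at least 1 in both lines were 237 genes, against 75.4 if independent. The sharing of the class is thus not separated from that of large falls. The genes named here beyond the rule are the members of the class in those lists. The tests of the class, of centring and of gene length were chosen only after the result was seen, as was the split of neighbours by whether the heat shock gene was called higher, whereas the other tests on neighbours and that on summed counts were written before.

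Several genes next to heat shock genes gained RPB1 and others lost it. MRPS14, less than 1 kb from the co-chaperone gene CACYBP, rose by 2.08 in HEK and 2.55 in K562 in the authors' deposited table. TECR, whose annotated span overlaps that of DNAJB1, rose by 1.66 and 1.70 in the authors' deposited table. BAZ2A, 25.0 kb from PTGES3, rose by 0.47 in HEK and 1.90 in K562 in the authors' deposited table. C6orf48, 4.66 kb from HSPA1B, fell by 0.99 in HEK and fell by 1.71 in K562 in the authors' deposited table. These neighbours were chosen after their values were seen.

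Polymerase running on from an induced heat shock gene is a candidate explanation for part of these rises. Within 50 kb of any chaperone-list gene 11 of 37 HEK and 10 of 35 K562 genes were called higher (Fisher's exact test against all other genes, odds ratios 5.04 and 4.26, p = 8.22e-05 and 0.000564). Within 50 kb of a list gene called higher it was 7 of 18 and 8 of 22 (odds ratios 7.58 and 6.09, Fisher's exact test, p = 0.000255 and 0.000326), and near list genes not called higher or not listed it was 4 of 19 and 2 of 13 (odds ratios 3.18 and 1.94, Fisher's exact test, p = 0.0549 and 0.309), a contrast that was not itself tested. In K562 all 13 listed members of the list were higher, so the second group there held only neighbours of unlisted genes. In HEK that group held neighbours of CDC37 and DNAJA4 and otherwise of unlisted genes. Unlisted genes have no fold change, so the contrast does not set induced against uninduced heat shock genes. Overlapping annotation is argued against as the whole cause, since for neighbours at least 1 kb away the odds ratios by Fisher's exact test were 4.29 and 3.55 (p = 0.000917 and 0.00489). A wider region of raised signal cannot be told apart, because against genes 200 to 500 kb away the odds ratios by Fisher's exact test were 2.89 (p = 0.0377, 95% interval 0.985 to 8.62) and 1.46 (p = 0.460). HEK met the prediction against that explanation by its p, but its interval includes 1, and neighbours that respond to heat shock through their own promoters stay open, untested. All these windows took neighbours on both sides of a heat shock gene without regard to strand. Run-on would reach only genes downstream of it, so these odds ratios do not tell run-on from other local causes.

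Of the genes called, 87.6% in HEK and 82.7% in K562 were lower after heat shock, and ribosomal protein genes were among them in both lines. A constant offset from scaling cannot be told apart from a general fall, since no outside standard is in the tables. The shares of calls that were lower after centring, 48.3% in HEK and 46.2% in K562, follow from the subtraction and decide nothing. For counts taken up by a few induced genes under a fixed total, the prediction was an unchanged sum of normalized counts over the listed genes. That sum fell instead, with log2 ratios of -0.31 in HEK and -0.15 in K562. It leaves out unlisted genes and reads outside genes, and the basis of its size factors is unknown, so it cannot decide the question. A general fall of engaged polymerase stays open, untested.

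For the less negative changes of the longest genes, polymerase already engaged when heat shock began and still crossing them stays open. The correlation of length with fold change was stronger above the median length than below it, by 0.321 in HEK and 0.259 in K562, but this split restates the trend that prompted it and lends that explanation no support. Short ribosomal protein and translation genes alone are argued against, since without the members of all lists rho across genes was 0.208 and 0.158. The higher total count of long genes is argued against in HEK, where the median rho within 10 groups of like mean normalized count was 0.260. It may account for the trend in K562, where that value was -0.0391. Among genes of like total count a longer gene has fewer reads per kb. The grouping therefore does not hold the density of reads equal, and a part played by density stays open, untested. Genes are not independent replicates, and the duration of heat shock, on which the first explanation turns, is not given in the sources used here.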
